A study of Homo sapiens with 4 samples.

How the data were processed

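Poly(A)-selected RNA of HCC1937 cells with an empty vector or with restored wild-type BRCA1, each under DMSO or OTX-015, was sequenced from 1 library per group, 4 libraries in all. Libraries were made with a directional kit, per the labels' protocols, and whether strand was used in quantification is not given in the sources used here. FPKM values per gene were computed by the authors with TopHat2 and Cufflinks on hg38, per the submitters' processing notes, and versions, annotation release and any scaling between libraries are not given there. Each deposited file held 60487 genes with an Ensembl identifier, a symbol and a locus. The files held no counts, confidence intervals or quantification status, so the depth of each library is unknown. A look for a common step in low values, limited to genes below 0.3 FPKM in the 3 pairs with the vector DMSO library, found at most 4 of 229 genes with the same ratio after rounding to 3 decimals.

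Values were joined by gene identifier, of which 94.2% (56993) were in GENCODE 29. The 7512 short structural RNA genes were left out, and genes sharing a symbol (68 symbols) were summed. Genes with an FPKM of at least 1 in at least 1 library were kept (18295) and analysed as log2(FPKM + 1). A log2 difference on this scale understates changes of low genes. limma (version 3.58.1, R 4.3.3) was fitted to the log2 values with line and treatment as terms and the mean-variance trend in the empirical Bayes step, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. This leaves 1 residual degree of freedom per gene, pooled over genes, and the residual holds the difference between the lines' responses. The adjusted p therefore measures consistency across the other factor and not the spread between repeated cultures. Rose, fell and changed refer to this fit. Pairs of libraries and the difference of responses had no test and are given as genes with a log2 difference of at least 1. The procedure was tested on simulated data of 18295 genes with 200 changed. For the OTX-015 effect it recovered 0%, 44%, 84% and 98% of genes changed by 1, 2, 3 and 4 log2 units with 0 false calls. For the wtBRCA1 effect it recovered 2%, 72%, 98% and 100%, with 7.5% of calls false. Each effect had 1 simulated data set from the same noise model, so the gap between these rates may be random draw and does not rank the 2 tests. The simulated noise was drawn from the fit's own estimate of the spread, with no difference of response between the lines. Only genes above a minimum mean level were changed. The simulated data thus met the assumptions of the fit, so these rates need not hold for the real libraries.

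The medians of 33 gene lists are set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The genes named were chosen by rule: the 12 highest and 12 lowest for OTX-015 in both lines and the 10 highest and 10 lowest for wtBRCA1, by mean log2 difference among genes past the threshold with the same sign and at least 1 log2 unit in both comparisons and an FPKM of at least 5 in a library, the 8 most extreme each way for the difference of responses, and from each list up to 5 members from the highest and lowest ends, or any member of the BET, redox and homologous recombination lists. Clone-named, short structural, X-inactivation and Y-linked genes were left out of that rule, and some members of the lists are not reported here. Gene lists, model, filter, pseudocount and this rule were fixed before the data were examined. Alternatives covered pseudocounts of 0.1 and 5, an FPKM filter of 5 or none, median-of-ratios and quantile scaling, the row with the highest mean per symbol, the trend, robust estimation, the other factor left out, and each library left out. Restriction to genes with a transcript of at least 300 nt and to protein-coding genes was chosen after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.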

Results

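RNA was profiled in HCC1937 cells, an established human breast cancer line that lacks functional BRCA1, carrying either an empty vector or restored wild-type BRCA1 (wtBRCA1). Each line was treated with the solvent DMSO or with OTX-015 (birabresib), an inhibitor of the BET bromodomain proteins, which read acetylated histones. The 4 groups have 1 library each, so no value has a replicate, and no comparison of a pair of libraries was tested. The files hold FPKM values for 60487 genes per library, and the sequencing depth is unknown. The FPKM values summed to 909314 in vector cells under DMSO, 1496107 in vector cells under OTX-015, 962378 in wtBRCA1 cells under DMSO and 1477103 in wtBRCA1 cells under OTX-015. Genes at 1 FPKM or more numbered 15311, 15004, 15669 and 15311 in the same order. The 10 highest genes took 17.4% and 15.3% of the summed FPKM in the DMSO libraries and 39.2% and 33.8% in the OTX-015 libraries of vector and wtBRCA1 cells. A clone-named entry at the ferritin light chain locus, AC026803.1, held 3.7%, 17.3%, 2.6% and 14.8% of the summed FPKM in the 4 libraries and was singled out after its values were seen. Short structural RNA genes held 2.37% and 2.67% in the vector line and 5.55% and 5.72% in the wtBRCA1 line.

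BRCA1 (ENSG00000012048, chromosome 17, 43044295 to 43170245 in GENCODE 29, hg38) was listed at 37.2 FPKM in vector cells under DMSO and 40.8 under OTX-015. In the wtBRCA1 line it was listed at 171 FPKM under DMSO and 2712 under OTX-015. The wtBRCA1 to vector ratio was 4.6 under DMSO and 66.4 under OTX-015, and the direction of the line labels held in both treatments. Within the wtBRCA1 line the OTX-015 library was 15.8 times the DMSO library, against 1.1 times in the vector line. On the log2 scale the line effect was 4.10 ± 0.67 (SE, limma adjusted p = 0.00666), and the OTX-015 effect common to both lines was 2.06 ± 0.67 and did not pass the test (limma adjusted p = 0.104).

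**Figure D1:**
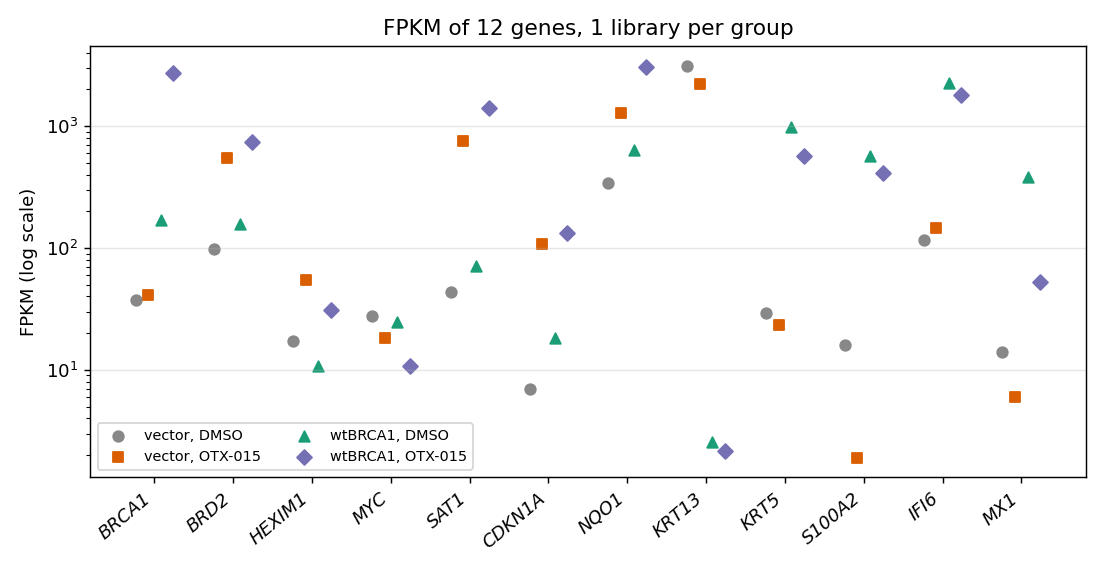
FPKM on a log axis of 12 genes in the 4 libraries, with 1 point per library. BRCA1 stands at 2712 FPKM in wtBRCA1 cells under OTX-015 and at 37.2 in vector cells under DMSO, and KRT13 is at 3141 and 2199 FPKM in the vector line against 2.58 and 2.15 in the wtBRCA1 line.

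The first comparison asked which transcripts OTX-015 changed in both lines. SAT1, the acetyltransferase that opens polyamine catabolism, rose from 43.4 to 760 FPKM in vector cells and from 71.6 to 1400 in wtBRCA1 cells, an effect of 4.19 ± 0.24 log2 (SE, limma adjusted p = 5.77e-05). SLC6A8, the creatine transporter, rose by 4.59 ± 0.36 log2, and DGAT1, which makes triglycerides, by 3.82 ± 0.28. TAX1BP3 rose by 3.70, the secreted chaperone CLU by 3.69, the sterol reductase TM7SF2 by 3.68, the matricellular gene CTGF by 4.49 ± 0.60, SERPINI1 by 3.64 and the histone gene HIST1H4H by 3.66. HIST1H2AL, the pseudogene DAP3P1 and the collagenase MMP1 also rose, and each was listed at 0 in at least 1 DMSO library, so no fold is given. In vector cells HIST1H2AL was at 0 and 28.4 FPKM under DMSO and OTX-015, DAP3P1 at 0 and 74.5, and MMP1 at 0 and 6.29. In wtBRCA1 cells the 3 genes were at 2.67 and 92.1, at 0 and 5.45, and at 0.652 and 25.2 FPKM. LSM5, a component of the LSM ring that binds RNA, fell by 3.79 ± 0.36 log2 (172 to 7.68 and 118 to 11.4 FPKM). Also lower were CSF1, the growth factor of macrophages (-3.31 log2), TMEM9 (-3.70 ± 0.58), MIR205HG (-3.27), the cell surface protein LY6D (-3.22), EPSTI1 (-3.17), the basal keratin KRT15 (-3.07), CAPN8 (-3.01) and ALKBH3, which repairs alkylated nucleic acids (-2.99). TM4SF18 (19.0 to 0 and 59.4 to 1.05 FPKM), PPP1R1C (16.2 to 0 and 54.9 to 8.08) and the pseudogene HDGFP1 (13.8 to 2.49 and 15.04 to 0) fell to a value listed at 0 in 1 library each. These 24 genes were past an adjusted p of 0.05 in the limma fit, with adjusted p from 5.77e-05 for SAT1 to 0.0124 for KRT15. Of the 12 that rose and the 12 that fell, 0 and 0 kept the call without the mean-variance trend, 7 and 5 after quantile normalization and 7 and 4 with no filter on low values. Of the 98 list genes past the threshold for OTX-015, 0, 8 and 8 kept the call in these 3 settings, 51 with a pseudocount of 5, 63 at an FPKM filter of 5, 74 with a pseudocount of 0.1 and 77 after median-of-ratios rescaling, so nearly all list calls given next depend on these choices. Among genes of the same locus above 10 FPKM, CTGF shares its locus with RP11-69I8.3 (up to 254 FPKM), DGAT1 with HSF1 (993), TM7SF2 with AP003068.9 (354), LY6D with RP11-706C16.8 (187), TAX1BP3 with P2RX5-TAX1BP3 (68.7), HIST1H2AL with Z98744.2 (24.6) and MMP1 with WTAPP1 (19.8), so reads could have been divided among them.

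Among the BET and P-TEFb genes, which act on transcription elongation, BRD2 rose from 97.52 to 552 FPKM in vector cells and from 159 to 743 in wtBRCA1 cells, an effect of 2.35 ± 0.23 log2 (SE, limma adjusted p = 0.00136). HEXIM1, the inhibitor of P-TEFb, rose by 1.53 ± 0.33 log2 (limma adjusted p = 0.0272). HEXIM2 (-1.70 ± 0.36) and LARP7 (-1.29 ± 0.32) fell, and the other 10 of the 14 measured members did not pass the test. Adjusted over the list alone, 5 rose and 2 fell. MYC was at 27.4 and 18.2 FPKM in vector cells and at 24.8 and 10.8 in wtBRCA1 cells, a difference of -0.85 ± 0.35 log2 (limma adjusted p = 0.179). Of the 12 measured transcripts commonly lower under BET inhibitors, 1 fell (3 adjusted over the list alone), with medians of -0.35 log2 in vector cells (percentile 8.47 among random lists) and -0.59 in wtBRCA1 cells (percentile 2.34). CCND1 was at 93.0 and 33.0 FPKM in vector cells and at 89.6 and 59.2 in wtBRCA1 cells.

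Most histone genes were higher under OTX-015. Of 14 measured members, 9 rose in the limma fit over both lines, none fell and 5 did not pass (11 and 0 adjusted over the list alone). The 9 calls came to 0 without the trend, 1 after quantile normalization and 2 with no filter. The medians were 2.20 log2 in vector cells and 2.0 in wtBRCA1 cells, both at percentile 100 of random lists. HIST1H1C, a linker histone, rose from 8.47 to 69.4 and from 26.9 to 252 FPKM. Poly(A) selection captures most replication-dependent histone mRNAs poorly. Of the p53 targets and CDK inhibitors, 6 of 22 rose and none fell (6 rose and 1 fell adjusted over the list alone). The CDK inhibitor CDKN1A rose from 6.93 to 107 FPKM and from 18.1 to 133 (3.29 ± 0.35 log2, SE, limma adjusted p = 0.00184), the ribonucleotide reductase subunit RRM2B by 2.35 and the mitochondrial reductase FDXR by 1.75 log2. CDKN2A was at 92.0 and 36.8 FPKM in vector cells and at 88.2 and 49.4 in wtBRCA1 cells and did not pass. The list medians were 0.65 and 0.68 log2 (percentiles 99.84 and 99.82).

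Of 28 thioredoxin and NRF2 redox genes, 9 rose and none fell (11 rose and 2 fell adjusted over the list alone). NQO1, a quinone reductase, rose from 341 to 1292 FPKM in vector cells and from 633 to 3067 in wtBRCA1 cells, an effect of 2.10 ± 0.19 log2 (SE, limma adjusted p = 0.000812). GCLC, which begins glutathione synthesis, rose by 2.31 log2, the heme oxygenase HMOX1 by 2.07, ARRDC4 by 2.58, TXNRD1 by 1.80, GPX4 by 1.81, PRDX1 by 1.54 and SOD1 by 1.12. TXNIP, the thioredoxin-binding protein, was at 29.1 and 74.9 FPKM in vector cells and at 48.2 and 91.6 in wtBRCA1 cells, with a difference of 1.12 ± 0.30 log2 (limma adjusted p = 0.06). The medians were 0.53 log2 (percentile 98.22) and 0.43 (percentile 95.99).

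Of 17 genes of the ER unfolded protein response, 6 rose and none fell (9 and 0 adjusted over the list alone), with medians of 0.98 and 0.73 log2 (percentiles 99.99 and 99.51). Of the 6 calls, 2 were kept after median-of-ratios rescaling, 2 with a pseudocount of 0.1 or of 5 and 2 at an FPKM filter of 5. CALR, an ER chaperone, rose by 1.28 and HYOU1 by 1.31 log2, while DNAJB11 was at 449 and 321 FPKM in vector cells and at 586 and 445 in wtBRCA1 cells. Of 23 autophagy and lysosome genes, 7 rose and none fell (9 and 0 adjusted over the list alone), with medians of 0.58 and 0.97 log2 (percentiles 99.09 and 100). The sialidase NEU1 rose by 2.42, GLA by 1.89 and the autophagy receptor SQSTM1 by 1.85 log2. Of 26 hypoxia and glycolysis genes, 6 rose and none fell (11 and 0 adjusted over the list alone), with medians of 0.66 and 0.61 log2 (percentiles 99.7 and 99.77). ADM rose by 1.76 and the pyruvate kinase PKM by 1.46 log2, and HK2 was at 8.52 and 7.85 FPKM in vector cells and at 6.18 and 2.49 in wtBRCA1 cells. Of 23 genes of the cholesterol biosynthesis list, which also held regulators of the pathway, 4 rose and none fell (7 and 0 adjusted over the list alone). The regulator INSIG1 rose by 2.87, IDI1 by 2.17 and SC5D by 1.83 log2. Mitochondrially encoded genes rose in 7 of 13 cases and none fell (12 and 0 adjusted over the list alone), with medians of 0.72 and 0.86 log2 (percentiles 96.62 and 99.49), beside the larger share of FPKM in the 10 highest genes of both OTX-015 libraries. Of these 7 calls, 2 were kept after median-of-ratios rescaling, 3 with a pseudocount of 0.1, 1 with a pseudocount of 5 and 3 at an FPKM filter of 5, and of the 6 hypoxia and glycolysis calls 3 with a pseudocount of 5. AP-1 and immediate early genes had 2 of 20 members that rose, JUND and ATF3, by 1.98 and 1.97 log2 (3 adjusted over the list alone), with medians of 0.82 and 0.47 (percentiles 99.98 and 97.82).

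The mitosis list had medians under OTX-015 of -0.43 log2 in vector cells (percentile 0.15) and -0.47 in wtBRCA1 cells (percentile 0.06). Of 30 members, 27 did not pass, none rose and 3 fell (6 adjusted over the list alone), the transcription factor FOXM1 (-1.42 ± 0.29 log2, SE), UBE2C (-1.13) and TOP2A (-1.10), and 1 of the 3 calls was kept with a pseudocount of 0.1 or of 5. CENPE and NUSAP1 had differences of 0.55 and 0.54 log2 and did not pass. Of 30 interferon-stimulated genes, 9 fell, none rose and 21 did not pass (13 fell and 2 rose adjusted over the list alone), with medians of -0.49 and -1.28 log2 (percentiles 0.1 and 0). Those that fell include IFIT1, an RNA-binding antiviral protein (-2.65 ± 0.36 log2, SE), and IFI44 (-2.49), and 2 of the 9 calls were kept with a pseudocount of 5. Of 34 DNA replication genes, 2 fell, MCM5 (-1.34 log2) and POLE2 (-1.82), and the count was also 2 adjusted over the list alone. Homologous recombination genes had 0 of 25 members past the limma adjusted p of 0.05, and 0 adjusted over the list alone, with medians of -0.07 and -0.42 log2 (percentiles 25.75 and 1.8). BRCA2 was at 2.04 and 4.65 FPKM in vector cells and at 8.82 and 5.97 in wtBRCA1 cells. The Fanconi anaemia list had 1 of 16 members that fell, FANCD2, with -1.54 log2 (1 adjusted over the list alone), and the end joining list had 1 of 13 that rose (1 adjusted over the list alone).

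Across 18295 genes, 669 rose and 488 fell under OTX-015 in the additive limma fit over both lines (2303 and 1867 at an unadjusted p under 0.05). In vector cells 2375 genes were at least 2-fold higher and 2324 lower, and in wtBRCA1 cells 2370 and 2453, with no test. The 2 lines' differences share no library. Across genes, which are not independent replicates, they had a Pearson r of 0.424 and a Spearman rho of 0.443, and 837 genes were at least 2-fold higher in both lines against 307.7 for independent lists, with 810 lower in both against 311.6. Opposite differences of that size numbered 101 and 94. The count of 1157 changed genes fell to 4 without the mean-variance trend, to 67 after quantile normalization, to 81 with no filter on low values, to 453 with a pseudocount of 5, to 522 at an FPKM filter of 5, to 756 with a pseudocount of 0.1, to 1 without the line term and to 0 when that term and any 1 of the 4 libraries were left out together. Median-of-ratios rescaling, which removed 0.11 log2 in vector and 0.09 in wtBRCA1 cells, gave 396 higher and 414 lower, and 2-fold counts of 2060 higher and 2632 lower in vector cells and 2103 and 2682 in wtBRCA1 cells.

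**Figure D2:**
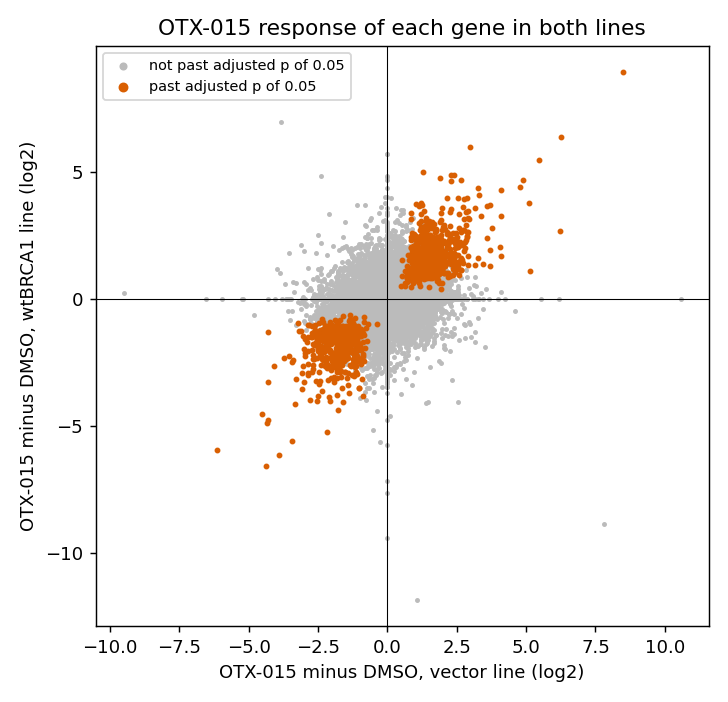
Log2 difference between OTX-015 and DMSO of each of 18295 genes in the vector line (horizontal axis) and in the wtBRCA1 line (vertical axis), with orange points for genes past an adjusted p of 0.05 in the limma fit. The 669 genes that rose and the 488 that fell lie in the upper right and lower left, and the correlation across genes is 0.424.

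The second comparison asked which transcripts differed between the wtBRCA1 and vector lines under both treatments. KRT13, a keratin of stratified epithelium, fell from 3141 to 2.58 FPKM under DMSO and from 2199 to 2.15 under OTX-015, an effect of -9.61 ± 0.28 log2 (SE, limma adjusted p = 2.08e-07). KRT81 was lower by -7.19 log2, the uroplakin UPK1B was at 136 and 61.8 FPKM in the vector line against 0.12 and 0, LYPD2 was lower by -5.68, the luminal keratin KRT19 by -5.63, the transglutaminase TGM2 by -5.59, MAL by -5.28, PSCA by -5.11, BASP1 by -4.88 and the matricellular gene SPARC was at 36.4 and 38.6 FPKM against 0.452 and 0. S100A2, a calcium-binding protein of basal cells, rose from 16.1 to 572 and from 1.91 to 412 FPKM (6.11 ± 0.45 log2, SE, limma adjusted p = 7.93e-05). RBM23 rose by 5.28 log2. Listed at 0 in both vector libraries were the imprinted genes SNRPN (51.6 and 150 FPKM in the wtBRCA1 line) and SNURF (32.2 and 46.3), C1orf21 (93.2 and 49.9), NPNT (32.0 and 45.5) and the neprilysin gene MME (32.5 and 40.1). TPM2, a tropomyosin, was at 0.107 and 0 FPKM in the vector line against 102 and 139, the transferrin gene TF at 0.306 and 0 against 32.5 and 55.1, and EPB41L2 at 0.504 and 0 against 39.9 and 50.1. All 20 were past the limma adjusted p of 0.05, with the highest adjusted p 0.000231 for PSCA. The 2 treatments are no replicates of the restoration of BRCA1. These p-values and the calls between the lines given next therefore cannot tell BRCA1 apart from other differences between the 2 lines. Among genes of the same locus above 10 FPKM, KRT13 shares its locus with AC019349.5 (up to 18038 FPKM), KRT81 with AC021066.1 (18046), RBM23 with PRMT5-AS1 (335), TGM2 with RPRD1B (25.1), NPNT with ARHGEF38 (24.5), MME with MME-AS1 (22.1), PSCA with JRK (18.3) and SNRPN with SNURF, so reads could have been divided among them.

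Interferon-stimulated genes were higher in the wtBRCA1 line. Of 126 list genes past the threshold for the line, 20 kept the call without the mean-variance trend, 70 after quantile normalization, 50 with no filter, 74 with a pseudocount of 5 and 78 at an FPKM filter of 5, and of the 21 interferon calls 4, 9, 9, 10 and 12. Of 30 measured members, 21 rose and none fell (25 and 0 adjusted over the list alone), with medians of 2.19 log2 under DMSO and 1.35 under OTX-015, both at percentile 100 of random lists. IFI6 rose from 117 to 2253 and from 145 to 1816 FPKM (3.94 ± 0.23 log2, SE, limma adjusted p = 3.84e-05), MX1, an antiviral GTPase, by 3.80 and IFI27 by 3.44 log2. Histone genes had 11 of 14 members that rose and none that fell (12 and 0 adjusted over the list alone), with medians of 1.84 and 2.10 log2 (percentile 100 for both), HIST1H2BK by 2.90. Of the 11 histone calls, 0 were kept without the trend, 4 with no filter, 6 with a pseudocount of 5 and 10 after quantile normalization. Short structural RNA also took a larger share of the FPKM in both wtBRCA1 libraries (5.55% and 5.72% against 2.37% and 2.67%). Mitochondrially encoded genes rose in 7 of 13 cases and none fell (12 and 0 adjusted over the list alone), with medians of 0.72 and 0.86 log2 (percentiles 99.83 and 99.86), beside the same share. Of the 7 mitochondrial calls, 6 were kept after median-of-ratios rescaling, 2 after quantile normalization, 0 with no filter and 0 without the trend. Basal epithelial markers had 9 of 19 members that rose and 1 that fell (13 and 1 adjusted over the list alone), with medians of 2.58 and 0.90 log2 (percentile 100 for both). KRT5 rose from 29.4 to 980 and from 23.2 to 573 FPKM (4.79 ± 0.27 log2, SE), and KRT81 fell. The desmosomal cadherin DSC3 was at 0 and 0.0755 FPKM in the vector line and at 18.8 and 8.0 in the wtBRCA1 line. Luminal epithelial markers had 6 of 18 members that fell and none that rose (8 and 0 adjusted over the list alone), with medians of -1.12 and -0.61 log2 (percentiles 0 and 0.14). KRT18 (-2.12 log2) and CLDN3 (-2.01) fell, and TFF1 was at 17.5 and 18.4 FPKM in the vector line and listed at 0 in both wtBRCA1 libraries. Epithelial marker EPCAM was at 443 and 377 FPKM in the vector line and at 403 and 427 in the wtBRCA1 line.

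**Figure D3:**
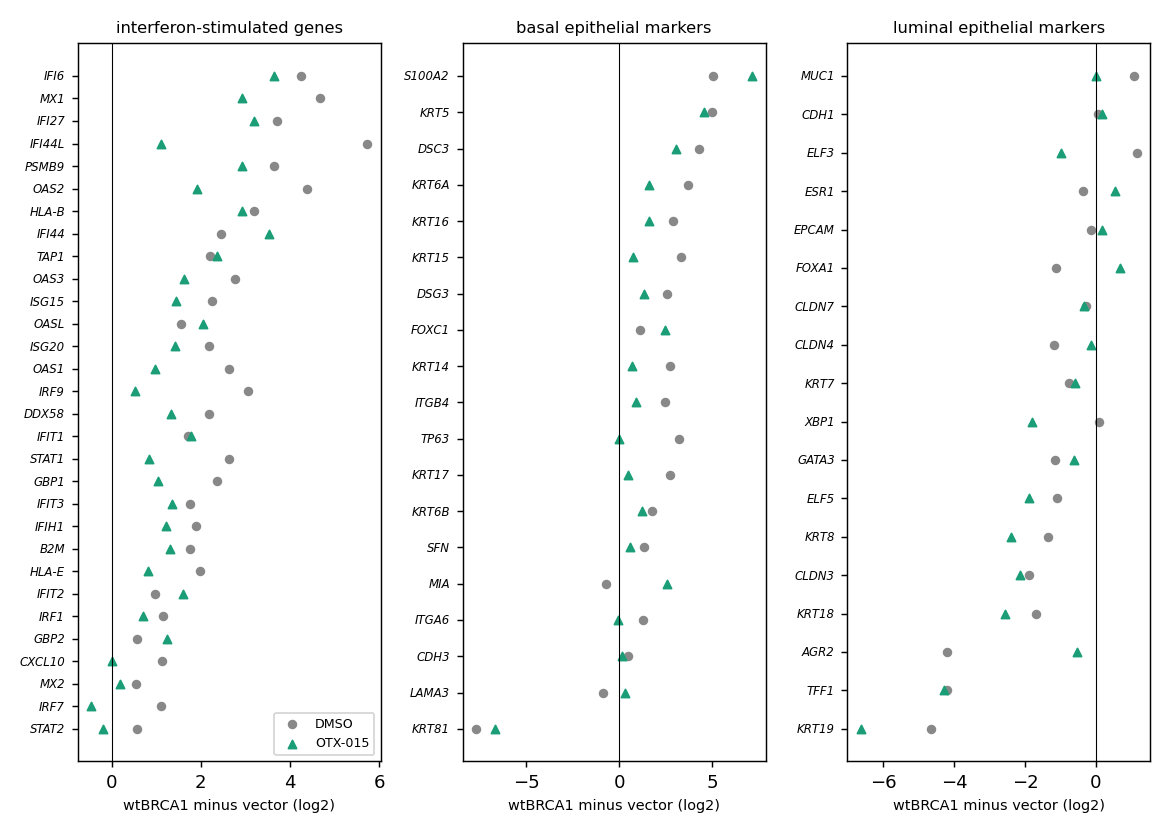
Log2 difference between the wtBRCA1 and vector lines of each member of the interferon-stimulated, basal and luminal lists, with grey circles for DMSO and green triangles for OTX-015 and 1 library per group. The interferon medians are 2.19 and 1.35, and the luminal medians are -1.12 and -0.61.

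Cholesterol biosynthesis genes had 5 of 23 members that fell and none that rose (7 fell and 1 rose adjusted over the list alone), with medians of -0.53 log2 under DMSO (percentile 0.06) and -0.18 under OTX-015 (percentile 11.17). HMGCS1 (-2.49 log2) and FDFT1 (-1.92) fell. Of 11 measured genes of the EGFR list, 3 fell, and 3 fell adjusted over the list alone. They were the ligand genes EREG (-3.90 ± 0.47 log2, SE) and TGFA (-1.46), and AXL (-3.91 ± 0.36), a receptor of another family that the list also held. Cytosolic ribosomal proteins had 5 of 28 members that fell and none that rose (8 and 0 adjusted over the list alone), with medians of -0.37 and -0.08 log2 (percentiles 0.13 and 11.08). RPLP2 (-1.52 log2), RPL27 (-1.74) and RPSA (-1.94) were among them. Of 26 mesenchymal and matrix genes, 4 rose and 4 fell (8 and 4 adjusted over the list alone), TNC by 3.03 and TGFBI by 2.45 upward and COL6A1 by -2.81 log2. NF-kB targets and cytokines had 3 of 22 members that rose, SAA1 by 3.42, LCN2 by 2.17 and IL32 by 2.08 log2 (4 rose and 1 fell adjusted over the list alone), with medians of 0.64 and 0 (percentiles 99.27 and 41.74). Of 25 homologous recombination genes, 2 fell, RAD51B (-2.35 log2) and MRE11A (-1.59), and 2 adjusted over the list alone, with medians of 0.11 and -0.09 (percentiles 62.05 and 31.45). After median-of-ratios rescaling 2 of these 2 calls were kept, but 0 at an FPKM filter of 5 or with no filter. The number kept was also 0 with a pseudocount of 0.1 or of 5, after quantile normalization and without the trend.

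The additive limma fit called 893 genes higher and 623 lower in the wtBRCA1 line (2414 and 1879 at an unadjusted p under 0.05). At least 2-fold differences, with no test, numbered 2715 higher and 2138 lower under DMSO and 2748 and 2312 under OTX-015. Across genes the 2 treatments' differences had a Pearson r of 0.514, and 1117 genes were higher in both against 407.8 for independent lists. Of the 15 immune markers 4 were measured, with CD14 at 0.109 and 0 FPKM in the vector line and at 9.51 and 5.62 in the wtBRCA1 line (limma adjusted p = 0.00523), and 5 of 11 endothelial and 5 of 14 fibroblast and muscle markers were measured, with none past the threshold in either comparison. The count of 1516 fell to 173 without the mean-variance trend, to 503 with no filter, to 697 after quantile normalization, to 861 with a pseudocount of 5, to 828 at an FPKM filter of 5, to 57 without the treatment term and to 0 when that term and any 1 of the 4 libraries were left out together.

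**Figure D4:**
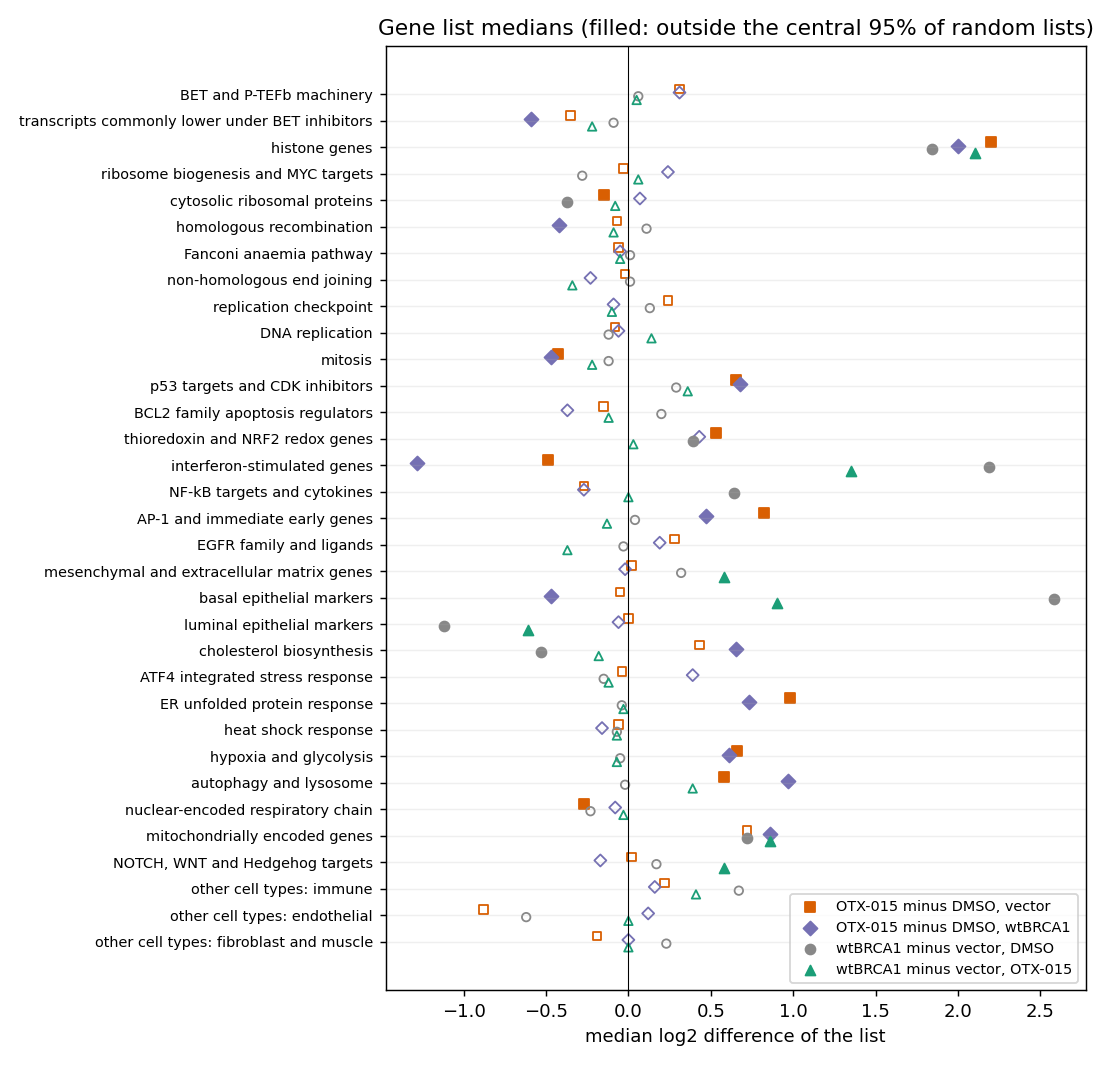
Median log2 difference of 33 gene lists (horizontal axis) for OTX-015 against DMSO in each line and for wtBRCA1 against vector under each treatment, with filled symbols for medians outside the central 95% of random lists matched on expression. Of 132 medians, 40 are filled, against 6.6 for lists of unrelated genes, and the interferon list lies at 2.19 and 1.35 for the line comparisons. Members of a list can change together and the 4 pairwise comparisons share libraries, so the 2 counts are a description and no test.

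The third comparison asked whether the lines responded differently to OTX-015, which 4 libraries cannot test. The response in wtBRCA1 cells was at least 2-fold above that in vector cells for 2411 genes and at least 2-fold below it for 2569. Metallothionein MT1X was at 11.95 and 0 FPKM in vector cells and at 10.2 and 15.8 in wtBRCA1 cells under DMSO and OTX-015. MT1X shares its locus with NUP93 (up to 128 FPKM), so reads could have been divided among them. TFPI2, a protease inhibitor, was at 4.16 and 3.86 FPKM in vector cells and at 3.99 and 79.8 in wtBRCA1 cells, a difference of responses of 4.10 log2. SNHG25, a host transcript of small nucleolar RNA, was at 36.4 FPKM in vector cells under DMSO and listed at 0 in the other 3 libraries. GTF2H2, a subunit of the transcription factor TFIIH, was at 1.27 and 53.4 FPKM in vector cells and at 1.67 and 0.914 in wtBRCA1 cells. The interferon-induced gene IFI44L was at 0.431 and 0 FPKM in vector cells and at 74.7 and 1.16 in wtBRCA1 cells. The median difference of responses was -0.74 log2 for interferon-stimulated genes (percentile 0.01), -1.23 for basal markers (percentile 0), 0.58 for ATF4 stress genes (percentile 99.82), 0.36 for cholesterol biosynthesis (percentile 98.18) and 0.32 for cytosolic ribosomal proteins (percentile 99.5). Histone genes had a median of 0.45, which turned negative with a pseudocount of 0.1. Basal marker TP63 was at 0.147 and 0 FPKM in vector cells and at 9.93 and 0 in wtBRCA1 cells. Members near 0 in vector cells under DMSO, such as TP63 and IFI44L, had little room to fall there. The random lists were matched on mean expression and not on the vector level, so the interferon and basal percentiles do not remove this limit.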

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

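The tests below were chosen after the result was seen. Of the 16 genes named for the difference of responses, 11 were higher under OTX-015 in 1 line and lower in the other by at least 1 unit of log2(FPKM + 1), and the difference was not tested. On that scale the response in wtBRCA1 cells minus that in vector cells was 10.82 log2 for the pseudogene RSU1P1, 5.37 for FGD3, 5.23 for the pseudogene SNRPGP2, 5.02 for RBM14-RBM4 and 4.79 for GPN2. It was -5.5 for TGIF2-C20orf24, -5.5 for URGCP-MRPS24, -4.83 for HMSD, -4.45 for C5orf56, -4.43 for SNHG9 and -4.33 for the pseudogene CYCSP55. RSU1P1, SNRPGP2, RBM14-RBM4, TGIF2-C20orf24, URGCP-MRPS24 and CYCSP55 were listed at 0 in at least 1 library, so their values are no folds and their size depends on the pseudocount. FGD3 went from 18.2 to 0.63 FPKM in vector cells and from 1.22 to 6.81 in wtBRCA1 cells. SNHG9 went from 3.97 to 43.1 and from 6.78 to 2.19 FPKM. Among genes of the same locus above 10 FPKM, TGIF2-C20orf24 shares its locus with C20orf24 (up to 295 FPKM) and URGCP-MRPS24 with MRPS24 (204). RBM14-RBM4 shares its locus with RBM4 (41.9) and GPN2 with RP1-50O24.6 (17.0).

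Of the 11 genes, 9 (81.8%) are pseudogenes or share a locus with another gene above 0, against 67.1% of 12513 other genes at 5 FPKM or more (Fisher's exact test, 2-sided, p = 0.522), so reads divided among overlapping or related genes may have contributed, and the test does not decide it. The 12513 genes also include clone-named ones, which the naming rule had left out, so the 2 sets were not drawn alike. Opposite differences of at least 2-fold were found for 130 genes at 5 FPKM or more, against 433.1 if the 2 responses were unrelated. With 1 library per group, chance spread between libraries and a difference in the response of the lines cannot be told apart.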

How the results depend on the processing

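Restriction by transcript length or to protein-coding genes was chosen after the data were seen. The OTX-015 count of 1157 was 756 and 453 with pseudocounts of 0.1 and 5, 81 with no filter, 522 at an FPKM filter of 5, 67 after quantile normalization, 4 without the trend and 1 without the line term. The wtBRCA1 count of 1516 was 861 with a pseudocount of 5, 503 with no filter, 828 at a filter of 5, 697 after quantile normalization, 173 without the trend and 57 without the treatment term. Without each library in turn, fitted without the other factor, both counts ranged from 0 to 0, so the left-out library and the dropped factor are not separated. The other alternatives gave counts within 1.5 times. With a pseudocount of 5 the 2-fold counts fell to 1847, 1944, 1970, 2012 and 1721 for OTX-015 in vector, in wtBRCA1, wtBRCA1 under DMSO, under OTX-015 and the difference of responses, and among protein-coding genes (fewer genes tested) to 2989, 3139, 3206, 3231 and 2901. The difference of responses was 2915 at a filter of 5. The cause was not tested otherwise. The correlation of responses ranged from 0.305 to 0.506, and 37 to 40 list medians lay outside the central 95%. The median of histone genes in the difference of responses reversed to -0.15 with a pseudocount of 0.1, and that of NOTCH, WNT and Hedgehog targets for wtBRCA1 under OTX-015 to -0.062 at a filter of 5. Rescaling turned the sign of 6 of 165 list medians, none above 0.1 in size. No named gene reversed, but of the 24 named for OTX-015 the call was kept by 0 without the trend, 12 after quantile normalization and 11 with no filter, against 20 of 20 for wtBRCA1 in each. Alternatives by confidence interval or quantification status were not run, since the files used here hold neither. Depth is unknown.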

Other observations

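The tests on BRCA1 and interferon-stimulated genes below were chosen after the result was seen. Some genes were on in 1 line and off in the other, at 10 FPKM or more in both libraries of a line and under 0.5 in both of the other. There were 17 such genes in the wtBRCA1 line and 6 in the vector line, and 0 by treatment in either direction. The vector group held KRT81, UPK1B, SPARC, TFF1, LINC01234 and the retinaldehyde dehydrogenase ALDH1A1 (14.3 and 18.9 FPKM against 0.349 and 0). LINC01234 and ALDH1A1 were named after their values were seen. FTL, the ferritin light chain, was at 645 and 1793 FPKM in vector cells and at 232 and 1103 in wtBRCA1 cells under DMSO and OTX-015, and it was named after its values were seen because AC026803.1 at the same locus reached 258769 FPKM.

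Several lists had few members past the threshold. Under OTX-015 the heat shock list had 1 of 14 members that rose, DNAJB1 by 1.33 log2, and 2 that fell, HSPB1 (-1.46) and HSPE1 (-1.35) (2 and 2 adjusted over the list alone). The ATF4 list had 1 of 18 members that rose, ASNS by 2.17 log2, and 1 that fell, NUPR1 (1 and 2 adjusted over the list alone). Ribosome biogenesis and MYC targets had 1 of 24 that rose, ODC1 by 1.16, and 1 that fell, WDR12, with -1.87 (1 and 1 adjusted over the list alone), and cytosolic ribosomal proteins had 0 of 28 past the threshold (0 adjusted over the list alone), with medians of -0.15 and 0.07 (percentiles 1.16 and 11.42). The nuclear-encoded respiratory chain had 1 of 27 that fell (also 1 adjusted over the list alone), with medians of -0.27 and -0.08 (percentiles 0.41 and 3.79). The BCL2 list (0 of 19), which also held XIAP, BIRC2, BIRC3 and CFLAR, and the replication checkpoint list (0 of 19) had none past the limma threshold, and 0 adjusted over the list alone. NOTCH, WNT and Hedgehog targets had 1 of 16 that fell, the WNT antagonist DKK1 (-1.98 log2, also 1 adjusted over the list alone), and DKK1 also fell in the wtBRCA1 line (-3.79). Mesenchymal and matrix genes had 3 of 26 that rose and 1 that fell, PLAU (3 and 2 adjusted over the list alone), and basal markers 2 of 19 that rose, KRT16 and SFN, and 1 that fell, KRT15 (3 and 2 adjusted over the list alone). The basal medians were -0.05 log2 in vector cells (percentile 24.46) and -0.47 in wtBRCA1 cells (percentile 0.69). Luminal markers had 2 of 18 that rose, CDH1 and KRT8, and 2 that fell, MUC1 and KRT7 (2 and 2 adjusted over the list alone). NF-kB targets had 1 of 22 that fell, CSF1 (1 adjusted over the list alone), and the EGFR list 0 of 11 (0 adjusted over the list alone).

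Between the lines, AP-1 and immediate early genes had 1 of 20 that rose, ATF3, and 3 that fell, the phosphatase genes DUSP4 (-2.57 log2), DUSP5 (-2.00) and DUSP1 (-1.81) (1 and 4 adjusted over the list alone). Redox genes had 4 of 28 that rose, among them AKR1C1 by 2.12 log2, and 3 that fell, among them GSR (-2.33) (5 and 4 adjusted over the list alone). The hypoxia and glycolysis list had 4 of 26 that rose and 2 that fell, LDHA (-1.26) and BNIP3L (-1.77) (5 and 3 adjusted over the list alone), and the autophagy and lysosome list 2 of 23 that rose and 1 that fell, CTSD (-1.22) (5 and 3 adjusted over the list alone). The p53 and CDK inhibitor list had 2 of 22 that rose, CDKN2C by 2.84 log2 and FDXR by 1.23, and the mitosis list 2 of 30, FOXM1 by 1.67 and NUSAP1 by 1.51, with 2 in each adjusted over the list alone. DNA replication genes had 2 of 34 that rose, CDT1 and RFC4, and 1 that fell, RRM1 (2 and 1 adjusted over the list alone). In the heat shock list HSPB1 and CRYAB rose (2 of 14, also 2 adjusted over the list alone), and in the ATF4 list 1 of 18 rose, PHGDH by 1.97 log2, and 2 fell, DDIT4 and TRIB3 (3 and 2 adjusted over the list alone). Ribosome biogenesis genes had 2 of 24 that fell, ODC1 (-1.93) and NOP56 (-0.96) (3 adjusted over the list alone), and the respiratory chain 1 of 27 each way, COX4I1 and COX7C (0 and 0 adjusted over the list alone). In the replication checkpoint list WEE1 (-1.85) and CDC25B (-1.42) fell (2 of 19, also 2 adjusted over the list alone), FANCD2 (-1.62) in the Fanconi list (1 of 16, with 1 and 1 adjusted over the list alone) and XRCC5 (-1.23) in the end joining list (1 of 13, also 1 adjusted over the list alone). Transcripts commonly lower under BET inhibitors had 2 of 12 that fell, HMGA2 and AREG (1 and 2 adjusted over the list alone), and NOTCH, WNT and Hedgehog targets 1 of 16 each way, TCF7 and DKK1 (2 and 1 adjusted over the list alone). BET and P-TEFb genes, the unfolded protein response and the BCL2 list had 0 members past the threshold between the lines, and 0 adjusted over the list alone.

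BRCA1 was 15.8 times as high under OTX-015 as under DMSO in the wtBRCA1 line. Among the other genes of the locus the highest, NBR1, was listed at 16.5 FPKM in that library against 2712 for BRCA1. Reads of a neighbour counted as BRCA1 would be missing from the neighbour's own value, so these values do not decide on a spill-over. Scaling of the libraries is argued against by a log2 difference of 3.89 after median-of-ratios rescaling. A response of the endogenous gene alike in both lines is argued against by the vector line, where BRCA1 was 1.1 times as high, a difference of 3.85 log2 between the lines' responses that 9 of 3584 genes at a similar level in vector cells (0.251%) reached in either direction. A candidate explanation that stays open is a response of the introduced BRCA1 sequence to OTX-015, which was not tested, and since no spread between cultures is known, a deviation of the 1 library at 2712 FPKM stays open too.

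Interferon-stimulated genes were higher in the wtBRCA1 line. The explanation that 1 deviating library, wtBRCA1 under DMSO, made the difference is argued against by the comparison under OTX-015, which does not use it and had a median of 1.35 log2 (percentile 100, 25 of 30 members at least 1.5-fold higher). Immune cells in the cultures are argued against by PTPRC, TYROBP, LYZ, AIF1, CD3D and CD79A, whose highest value in a wtBRCA1 library was 0.809 FPKM, although CD14 was at 9.51 FPKM. The further fall under OTX-015 in the wtBRCA1 line (median difference of responses -0.74 log2) may come from the 1 wtBRCA1 library under DMSO, which that response uses, and a second such library would be needed to tell. Members near 0 in vector cells under DMSO, such as IFI44L (0.431 FPKM), had little room to fall there. The median difference of responses is therefore no measure of a stronger response in the wtBRCA1 line. A difference between the lines other than BRCA1, such as clonal history, stays open and was not tested.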
